A study of Mus musculus with 10 samples.

How the data were processed

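RNA from mouse embryonic stem (ES) cells and from cultures differentiated from them toward the heart lineage was sequenced in 10 libraries. Per the labels, wild type and Rybp-null cells were sampled at day 0 (ES cells) and at days 8 and 14 of differentiation through hanging-drop embryoid bodies, with 1 library per genotype at day 0 and 2 per genotype at each later day. Total RNA was isolated with TRIzol and made into libraries with NuGEN Ovation and Encore kits, per the labels' protocols. The deposited table holds whole-number read counts per Ensembl gene, made by the authors and not normalized. TopHat, HTSeq and DESeq and the mouse build mm9 are named in the submitters' processing notes; their versions, the annotation release, the strand setting and the counting options are not given in the sources used here. Reads of a gene and of an antisense or overlapping gene, or of a gene and its processed pseudogene, therefore cannot be told apart, and genes with near-identical copies are treated as uncertain. This covers the ribosomal protein genes, which have pseudogenes, and the globin Hba-a1, which has the close copy Hba-a2.

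The table lists 36191 gene IDs, of which 30946 matched a symbol in the gene name table and 5245 did not; 7954 genes had 0 counts in all 10 libraries. Library totals ran from 3028153 to 6890792 counts, which is shallow. Levels are given in CPM, a count scaled to the size of its library, and at that depth a gene under a few CPM has a wide counting error. Where a group held 0 counts, a fold is given as a lower bound against a floor of 3 counts over the group's libraries together; where it held 1 to 3 counts, the ratio of pooled CPM is given with its 95% counting interval; where both groups held 3 counts or fewer no fold is given. These intervals and floors cover counting error only.

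Gene symbols came from the gene name table matched on Ensembl ID. Chromosome membership and the order of genes came from the GENCODE vM21 annotation, which is built on GRCm38 and not on mm9, so no coordinates are given. GC content and gene length, used for a single check, came from the same annotation.

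Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 15819 genes; libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion was fitted to all 10 libraries with 1 coefficient for each of the 6 genotype-by-day groups, leaving 4 residual degrees of freedom. The common biological coefficient of variation was 0.214. These tests were two-sided, p was adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were Rybp-null against wild type at day 8 and at day 14, the genotype-by-day interaction between those days, day 8 against day 0 in each genotype, and day 14 against day 8 in each genotype. Each adjusted p of a gene comes from this edgeR quasi-likelihood test. In the comparisons with day 0, the lone library of that day is assumed to vary like the other groups. At day 0 the genotypes were not tested; log2 ratios with a prior count of 2 are given for genes with at least 5 CPM in either library, counted at 4-fold or more, and the median of a gene list is placed among the medians of 10000 random lists of the same size matched on mean expression, as a description of these libraries. Overlaps of calls were compared with those of independent lists by Fisher's exact test. It was one-sided for calls shared by days 8 and 14 or shared by both genotypes, and two-sided otherwise. Standard errors of log2 fold changes are those implied by the test: the absolute log2 fold change over the square root of its F statistic. They restate the unadjusted p of the gene and are not separate estimates of error. Levels are mean CPM ± SD with n = 2 unless a single library is named.

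Before the data were examined, 37 gene lists were fixed, covering cell type markers, pathways and protein complexes; 36 had the minimum of 5 tested members. Each was tested against all other genes with camera (limma 3.58.1, inter-gene correlation preset to 0.01) and adjusted over the lists of that comparison. The same test with a correlation estimated from the data is given beside each list call, and fry, which asks whether the genes of a list move on balance in a single direction without comparing them with other genes, was run as a further alternative. With the estimated correlation no list passed in any of the 7 comparisons, and the lowest adjusted p was 0.1 at day 8, 0.29 at day 14, 0.29 for the interaction, 0.087 and 0.077 for day 8 against day 0 in wild type and null cells, and 0.46 and 0.37 for day 14 against day 8. Members of a list were counted as passing over all genes tested and when adjusted over the list alone.

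Genes are named by a rule set at the same time. Rybp, its paralog Yaf2, Plagl1, Isl1, Nkx2-5, Tnnt2, Myh6, Pou5f1 and Nanog are named whatever their p. In each genotype comparison the 8 largest changes in each direction were taken among called genes with a mean of at least 5 CPM and no overlap between the groups; in each day comparison and the interaction, 4 were taken. Unnamed clones, predicted genes and small RNAs were counted but not named. At day 0 the rule took the 6 largest ratios in each direction. From a list that passed, and from the lists of cardiac progenitors, sarcomere, calcium handling, pluripotency and Polycomb repressive complex 1, up to 4 members with the smallest p were taken, and up to 2 from any other list mentioned. Genes outside the rule are said to be chosen after their values were seen.

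The model was tested on simulated counts for the 15819 tested genes, with a single run per comparison. Each gene had the same mean share in all libraries, scaled to their depths, with the spread estimated from the data. From that start 100 genes were changed 2-fold and 100 changed 4-fold in a single group. At day 8 the model recovered 19% of the 2-fold and 61% of the 4-fold changes, with 10 unchanged genes called. At day 14 the shares were 18% and 62%, with 9 unchanged genes called, and for the interaction 3% and 43%, with 7. Day 8 against day 0 gave 6% and 48% in wild type cells, with 2 unchanged genes called, and 5% and 49% in null cells, with 17. Day 14 against day 8 gave 20% and 64% in wild type, with 15, and 19% and 75% in null cells, with 5. Unchanged genes made up 11.7% of the 557 simulated calls of the 7 comparisons and 23.9% of those of null day 8 against day 0, above the 5% aimed at. Because few genes were changed in the simulation, these shares do not carry over to comparisons where many genes change. The real comparison of null day 8 against day 0 had 5962 calls. As the recovered shares show, a moderate change often went uncalled in this setting, at the depth and replication of these libraries. In a simulated list shifted 2-fold at day 8 the list test gave an adjusted p of 3.61e-25, and 0 of 34 unshifted lists passed. The simulated genes were drawn independently of each other, so this does not measure false list calls among correlated genes.

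Alternatives were DESeq2 size factors, library totals alone, no filter on low counts, non-robust dispersion, the DESeq2 1.42.0 Wald test, each library of days 8 and 14 left out in turn, the replicate number as a block over 8 libraries, fits of those 8 libraries or of the 4 libraries of a single day, other prior counts and CPM minimums at day 0, and an adjusted p of 0.01 for overlaps of calls. A further alternative, without genes of chromosomes 1, 6, 8, 14 and Y, was chosen after seeing the data. Where a library is left out and a group keeps a single library, that library is assumed to vary like the other groups. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.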

Results

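RYBP is a zinc finger protein that binds RING1 proteins and is a core member of variant Polycomb repressive complex 1 (PRC1), which silences developmental genes. The transcriptomes of wild type and Rybp-null mouse ES cells, and of the cultures derived from them, were compared along differentiation toward cardiomyocytes, to ask how loss of Rybp changes that course. Each genotype was represented by 1 library at day 0 and by 2 libraries at each of days 8 and 14. Library totals were 3419681 counts for wild type at day 0, 3028153 and 3492732 at day 8, and 3143829 and 3812029 at day 14. For the null cells they were 6890792 at day 0, 4164476 and 3366320 at day 8, and 3311037 and 3951179 at day 14. The main axis of variation over the 500 most variable genes took 78.9% of the variance and set day 0 apart from the later days, and the next took 11.4% and set day 8 apart from day 14 in both genotypes. Replicates of a group differed by more than counting noise, with Spearman correlations across genes of 0.972 and 0.969 for wild type and 0.957 and 0.961 for null cultures at days 8 and 14.

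Rybp (ENSMUSG00000072872, chromosome 6) was close to absent from every null library, which held 1 to 4 counts each. Wild type levels were 76.2 CPM at day 0, 40.7 ± 3.39 CPM at day 8 and 21.5 ± 2.84 CPM at day 14, against 0.508, 0.386 ± 0.138 and 0.81 ± 0.447 CPM in the null cells. The wild type level was 104-fold that of null cultures at day 8 (95% counting interval 35.1 to 506, adjusted p = 1.92e-05), and at day 14 the log2 fold change was −4.71 (SE 0.43, adjusted p = 0.000338). Rybp-ps, a copy that may share reads with Rybp and is therefore uncertain, was lower as well, with wild type to null ratios of 174 (30.8 to 6930) at day 8 and 87.5 (15.3 to 3500) at day 14. Yaf2, the paralog of Rybp, had log2 fold changes of −0.36 (SE 0.32, adjusted p = 0.681) at day 8 and −0.38 (SE 0.31, adjusted p = 0.702) at day 14. Without any 1 of the 8 libraries of days 8 and 14, Rybp still passed at both days.

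At day 0, where each genotype had a single library and nothing was tested, the null ES cells held more transcripts of germline genes and less of the imprinted genes Meg3 and Plagl1. Of 10865 genes compared, 195 were at least 4-fold higher and 78 at least 4-fold lower in the null library. Genes were ranked by ratios with a prior count of 2, which shrinks them; ratios with an interval and bounds are printed without it. The largest ratios upward were those of the testis-expressed genes Tex13b (at least 20.3-fold) and Tex11 (29.3-fold with the prior count, 53.5 against 1.32 CPM), the X-linked lymphocyte-regulated genes Xlr4a (at least 11.3-fold) and Xlr4b (at least 10.3-fold), the protease inhibitor A2m (at least 19.3-fold) and the carbonic anhydrase Car12 (53.3-fold without it, 9.37 to 2130). The largest downward ratios, given as wild type over null, were 150 for Rybp (50.7 to 733), 112 for Rybp-ps (37.6 to 547), 68.2 for the ubiquitin ligase Trim36 (11.5 to 2770), at least 15.6 for the matrix protein Postn, 14.4 for the neural regulator Pax6 and 13.9 for the noncoding RNA Meg3. Plagl1, an imprinted zinc finger transcription factor, was at 4.91 CPM in the null and 66.3 CPM in the wild type library, a 12.3-fold difference with the prior count. Of 26 germline genes 21 were at least 2-fold higher in the null library, among them Dazl (13.5-fold), and the list's median log2 ratio of 1.76 lay at percentile 100 of random lists. Genes of the two-cell embryo stage were higher too, with a median of 2.96 at percentile 100, while PRC1 genes had a median of −0.22 at percentile 0.27. The embryo stage list was fixed with several members of families of close copies, such as Zscan4, which may share reads. Its value is therefore uncertain, as are those of Xlr4a and Xlr4b. The pluripotency genes stood at percentile 13.61, with Nanog 2.02-fold higher in the null library (8240 against 4090 CPM), Tbx3 4.72-fold higher and Pou5f1 at 154 against 172 CPM. Nanog lies on chromosome 6, whose genes were on the whole higher in null libraries. Sarcomere genes lay at percentile 39.85, calcium handling genes at 98.93 (median 0.4) and parietal endoderm genes at 99.89 (median 0.66).

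At day 8 several abundant muscle transcripts were far lower in null than in wild type cultures. Titin (Ttn), the giant spring of the sarcomere, was at 25.6 ± 8.16 CPM against 1090 ± 241 CPM, a log2 fold change of −5.42 (SE 0.28, adjusted p = 1.22e-06). The cardiac myosin heavy chains Myh6 (1.23 ± 0.708 against 181 ± 2.23 CPM) and Myh7 had log2 fold changes of −7.21 (SE 0.77) and −6.8 (SE 0.6), cardiac actin Actc1 −6.4 (SE 0.72), and cardiac troponin T, Tnnt2, −3.4 (SE 0.52, adjusted p = 0.0245). The myosin light chains Myl7 and Myl3 had 0 counts in the null libraries and were at least 40.3-fold and at least 25.8-fold lower, and the thin filament protein Nebl and the light chain Myl4 fell by 3.91 (SE 0.43) and 3.47 (SE 0.38). Of 36 sarcomere genes tested, 14 were lower, 0 were higher and 22 did not pass. Adjusted over the list alone 22 were lower. The median log2 fold change of the list was −2.15, or −1.98 with genes at 0 counts held at their bound. Such medians with bounds also leave out genes with 3 counts or fewer in both groups, so they can lie farther from 0. For the sarcomere list camera gave adjusted p = 6.87e-19, or adjusted p = 0.1 with an estimated correlation. Myh6 and Myh7 lie on chromosome 14 and Tnnt2 on chromosome 1, and 4 of the 14 lower sarcomere genes lie on chromosomes 1, 6, 8 and 14, whose genes were on the whole higher in null libraries.

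Some genes of calcium handling and of cardiac progenitors were also lower at day 8. Among 33 genes of calcium handling and ion channels, 4 were lower and 0 higher, with 7 lower and 1 higher adjusted over the list alone: the sodium-calcium exchanger Slc8a1 (log2 fold change −3.09, SE 0.32), the calcium release channel Ryr2 (−2.41, SE 0.28), the calcium-binding protein Hrc (−3.1, SE 0.44) and junctophilin Jph2 (−2.26, SE 0.37), with a list median of −0.5. For the calcium handling list camera gave adjusted p = 3.11e-05, or adjusted p = 0.19 with an estimated correlation. Among 29 cardiac progenitor genes and transcription factors 2 were lower and 0 higher, or 7 lower adjusted over the list alone. These were the muscle methyltransferase Smyd1 (−4.28, SE 0.32, adjusted p = 3.02e-05) and the GATA cofactor Zfpm2 (−1.27, SE 0.28, adjusted p = 0.0468). Mef2c and Meis1 were at −1.27 (adjusted p = 0.0662) and −0.97 (adjusted p = 0.0713), and the list median was −0.57. Smyd1 lies on chromosome 6, whose genes were on the whole higher in null libraries. For the cardiac progenitor list camera gave adjusted p = 6.72e-05, or adjusted p = 0.21 with an estimated correlation. Isl1, a marker of cardiac progenitors, was at 4.69 ± 1.51 CPM in null and 10.4 ± 0.705 CPM in wild type cultures, which did not pass (−1.15, SE 0.58, adjusted p = 0.42). Nkx2-5 was close to absent from the counts of both genotypes, with at most 1 count per group, too few to compare them. Smooth muscle genes had a median of −0.59 with 0 of 15 members passing and 1 higher and 4 lower adjusted over the list alone. Acta2 was at −0.91 (adjusted p = 0.138) and Synpo2 at −1.09 (adjusted p = 0.155). For the smooth muscle list camera gave adjusted p = 0.00303, or adjusted p = 0.43 with an estimated correlation.

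Plagl1 (ENSMUSG00000019817, chromosome 10) was among the most abundant transcripts of wild type cultures and was at 155 ± 8.52 CPM in null against 11800 ± 986 CPM in wild type cultures at day 8 (log2 fold change −6.26, SE 0.3, adjusted p = 1.2e-06). Of 24 imprinted genes 5 were lower and 1 higher, or 8 and 4 adjusted over the list alone, with a median of −0.28. For the imprinted list camera gave adjusted p = 0.0272, or adjusted p = 0.43 with an estimated correlation. Besides Plagl1 the lower ones included Meg3 (−3.67, SE 0.25, adjusted p = 1.92e-05) and Peg3 (−0.82, SE 0.14, adjusted p = 0.0174), and Phlda2, a placental growth regulator, was higher (2.66, SE 0.49, adjusted p = 0.0202). The macrophage genes Tyrobp (−4.36, SE 0.63) and Csf1r (−3.2, SE 0.52) were lower, as were the visceral endoderm and liver genes Afp and Apoa1, whose wild type to null ratios were 71.8 (12.4 to 2880) and 33.4 (11.1 to 165). The list of blood genes had 3 lower and 0 higher of 20 tested, 6 and 4 adjusted over the list alone, and did not pass (camera adjusted p = 0.896, direction down), with a median of 0.26 and a mean of −0.44.

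The genes that were higher in null cultures at day 8 were led by germline genes. Ddx4, Mael, Tex11 and Tex13b had 0 counts in the wild type libraries of that day and were at least 54.1-fold, 45.6-fold, 31.3-fold and 23.4-fold higher in the null libraries. Rnf17, a tudor domain protein of male germ cells, was at 63.6 ± 17.9 CPM against 1.08 ± 0.731 CPM (log2 fold change 5.87, SE 0.42, adjusted p = 1.92e-05), and the meiotic genes Sycp3 (3.88, SE 0.63), Meioc (3, SE 0.51) and Syce1 (ratio 29.8, 7.95 to 251) and the X-linked Mageb16 (3.46, SE 0.52) were higher. Of 26 germline genes 7 were higher and 0 lower, or 11 higher adjusted over the list alone. The median was 2.27, or 1.89 with bounds. For the germline list camera gave adjusted p = 1.24e-08, or adjusted p = 0.21 with an estimated correlation. Of those 7, 1 lies on chromosomes 1, 6, 8 and 14, Mael on chromosome 1, and Rnf17 is on chromosome 14. Among 28 pluripotency genes Dppa5a (3.22, SE 0.55, adjusted p = 0.0144) and Esrrb (ratio 10.8, 3.43 to 54.9) were higher and 0 were lower, or 3 higher and 1 lower adjusted over the list alone. Tdgf1 was at −1.83 (adjusted p = 0.14), Utf1 had a ratio of 7.02 (2.13 to 36.4, adjusted p = 0.144), Nanog was at 1.55 (SE 0.51, adjusted p = 0.229) and Pou5f1 at 1.13 (SE 0.6, adjusted p = 0.45). The list median was 0.98, or 0.87 with bounds. For the pluripotency list camera gave adjusted p = 0.00609, or adjusted p = 0.43 with an estimated correlation. Of its 28 members 11 lie on chromosomes 1, 6, 8 and 14, whose genes were on the whole higher in null libraries. Nanog is among these 11, while Dppa5a and Esrrb are not. Trophoblast genes had a median of 1.63, or 1.54 with bounds, with 1 of 11 higher, the keratin Krt7 (2.1, SE 0.39), and 6 higher adjusted over the list alone. The homeobox genes Rhox6 and Rhox9 were at 6.01 (adjusted p = 0.0929) and 5.88 (adjusted p = 0.161). For the trophoblast list camera gave adjusted p = 0.00168, or adjusted p = 0.43 with an estimated correlation. In PRC1 itself Bcor rose by 1.11 (SE 0.23, adjusted p = 0.0379), Cbx7 and Wdr5 were at 1.16 (adjusted p = 0.217) and 0.83 (adjusted p = 0.136), and of 33 members 1 was higher and 1, Rybp, lower, as also when adjusted over the list alone (camera adjusted p = 0.0867).

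A further 5 lists passed at day 8 with 0 members passing over all genes. Ribosomal protein genes, with Rpl32 at 0.69 (adjusted p = 0.0907), had a median of 0.27 over 33 genes and 0 members over the list alone. For the ribosomal list camera gave adjusted p = 0.000462, or adjusted p = 0.43 with an estimated correlation. Pseudogenes may share reads with the ribosomal protein genes, so the value of this list is uncertain. Interferon response genes, with Ifit1 at least 9.12-fold lower (adjusted p = 0.0903), had a median of −0.75, or −0.73 with bounds, with 1 lower of 16 over the list alone. For the interferon list camera gave adjusted p = 0.0024, or adjusted p = 0.63 with an estimated correlation. Glycolysis and hypoxia genes, with the aldolase Aldoa at −0.64 (adjusted p = 0.0776), had a median of −0.36 with 2 lower of 22 over the list alone. For the glycolysis list camera gave adjusted p = 0.0137, or adjusted p = 0.43 with an estimated correlation. Lipid and cholesterol synthesis genes, with the desaturase Scd2 at −0.64 (adjusted p = 0.0621), had a median of −0.24 with 1 lower of 17 over the list alone. For the lipid list camera gave adjusted p = 0.0242, or adjusted p = 0.64 with an estimated correlation. Skeletal muscle genes, with the troponin Tnni2 at −2.85 (adjusted p = 0.0685), had a median of −0.88 with 1 lower of 8 over the list alone. For the skeletal muscle list camera gave adjusted p = 0.0363, or adjusted p = 0.43 with an estimated correlation.

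Across all 15819 genes tested at day 8, 80 were higher and 120 lower in null cultures, 59 and 108 of them by at least 2-fold, and 2122 genes had an unadjusted p under 0.05. Genes of chromosomes 1, 6, 8 and 14 were on the whole higher in the null libraries: their median lay 0.35 (bootstrap SE 0.011) above that of other autosomes on the log2 scale. These 4 chromosomes carry 18.5% of the tested genes and 49 of the 80 higher calls, among them the replication factor Mcm6 (1.11, SE 0.16, adjusted p = 0.00674), but 18 of the 120 lower ones. Without the genes of chromosomes 1, 6, 8, 14 and Y, an alternative chosen after seeing the data, 24 genes were higher and 76 lower. In that setting 11 of the 13 lists that had passed camera at day 8 kept their call. The count depended on single libraries. It was 28 genes without wild type day 8 replicate 1, 71 without wild type day 8 replicate 2 and 324 without null day 8 replicate 2. Ttn, Myh7, Myl7, Nebl, Myl4, Slc8a1, Ryr2, Smyd1, Plagl1, Meg3, Mael and Rnf17 passed without any 1 of the 8 libraries of days 8 and 14. Without wild type day 8 replicate 1, Myh6 (−7.2), Actc1 (−6.41), Tnnt2 (−3.32), Hrc (−2.89), Jph2 (−2.24), Zfpm2 (−1.01), Tyrobp (−4.11), Csf1r (−2.55), Peg3 (−0.79), Phlda2 (2.02), Dppa5a (2.75), Krt7 (1.71), Bcor (1.03), Mcm6 (1.05), Sycp3 (3.97), Meioc (3.5) and Mageb16 (3) kept their direction and no longer passed, nor did Myl3, Ddx4, Tex11, Tex13b, Esrrb, Afp and Apoa1. Without wild type day 8 replicate 2 the same held for Tnnt2 (−3.48), Jph2 (−2.28), Zfpm2 (−1.5), Peg3 (−0.85), Dppa5a (4.06), Krt7 (2.69), Bcor (1.19), Mcm6 (1.18), Sycp3 (3.79) and Meioc (2.6) and for Esrrb, Syce1, Tex11 and Apoa1. Without null day 8 replicate 1 Myh6 (−6.69), Esrrb and Apoa1 no longer passed. Without null day 8 replicate 2 this held for Bcor (0.97), Krt7 (1.56), Phlda2 (2.19) and Zfpm2 (−1.05), and without either wild type day 14 replicate for Bcor, Esrrb and Zfpm2.

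**Figure D1:**
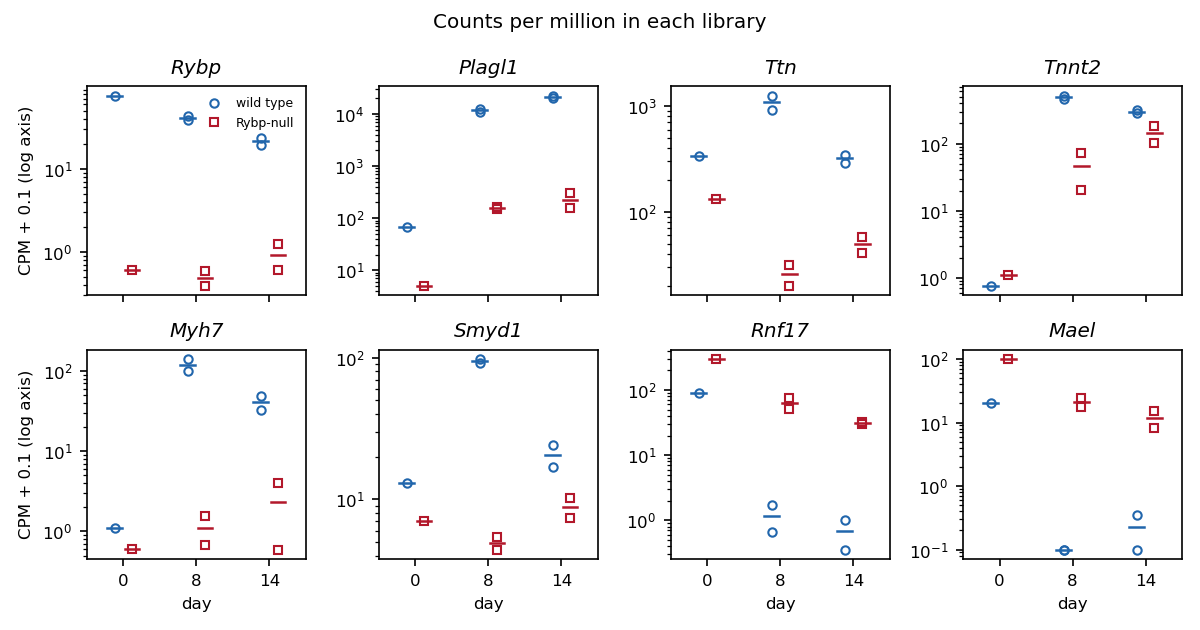
CPM plus 0.1 of 8 genes in each of the 10 libraries (log axis) by day, with circles for wild type, squares for Rybp-null and bars for group means. Ttn at day 8 averaged 1090 CPM in wild type and 25.6 CPM in null cultures, and Rnf17 averaged 1.08 and 63.6 CPM.

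At day 14 Plagl1, Meg3 and several muscle genes were again lower in null cultures. Plagl1 was at 227 ± 102 CPM in null and 21400 ± 1820 CPM in wild type cultures (log2 fold change −6.56, SE 0.3, adjusted p = 7.98e-07), and Meg3 fell by 3.85 (SE 0.26, adjusted p = 2.12e-05). Ttn was at 49.3 ± 12 against 320 ± 38.7 CPM (−2.69, SE 0.25, adjusted p = 0.000347), Myh7 at −4.23 (SE 0.54, adjusted p = 0.00572), Myh6 at −4.57 (SE 0.63, adjusted p = 0.0206), Actc1 at −4.78 (SE 0.68, adjusted p = 0.029) and the M-band protein Myom1 at −2.45 (SE 0.44, adjusted p = 0.0254). Of 36 sarcomere genes 6 were lower and 0 higher, 14 lower adjusted over the list alone, with a median of −1.28, or −1.08 with bounds. 2 of the 6, Myh6 and Myh7, lie on chromosome 14. For the sarcomere list camera gave adjusted p = 1.3e-08, or adjusted p = 0.29 with an estimated correlation. Tnnt2, at 142 ± 55.7 against 299 ± 26 CPM, did not pass (−1.08, SE 0.48, adjusted p = 0.397), and Smyd1 was at −1.23 (SE 0.3, adjusted p = 0.0972), Mef2c at −1.04 (adjusted p = 0.172), Irx3 at 1.55 (adjusted p = 0.115) and Eya1 at 1.12 (adjusted p = 0.135). Slc8a1 (−1.56, SE 0.29, adjusted p = 0.0338) and Ryr2 (−1.42, SE 0.29, adjusted p = 0.0488) were the 2 lower genes among 33 of calcium handling, which as a list did not pass (median −0.32, camera adjusted p = 0.0667, 2 higher and 5 lower adjusted over the list alone). Hrc and Jup were at −2.62 (adjusted p = 0.0621) and 1.03 (adjusted p = 0.101). The list of cardiac progenitor genes had 0 of 29 members passing, 3 higher and 3 lower adjusted over the list alone (median −0.1, camera adjusted p = 0.884). Isl1 had a wild type to null ratio of 7.38 (0.948 to 333).

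Germline genes were again higher at day 14. Rnf17 was at 31.2 ± 1.2 against 0.584 ± 0.465 CPM (log2 fold change 5.73, SE 0.48, adjusted p = 0.00015), Mael had a ratio of 85.4 (14.9 to 3410), and Syce1, Tdrd1 and Tex11, at 0 counts in wild type, were at least 19.9-fold, 13-fold and 24.7-fold higher. The germ cell transcription factor Taf7l (5.08, SE 0.78), Mageb16 (4.22, SE 0.54) and the phosphodiesterase Pde10a (4.08, SE 0.56) were higher as well. Of 26 germline genes 8 were higher and 0 lower, 11 adjusted over the list alone, with a median of 2.13, or 2.21 with bounds, and 1 of the 8, Mael, lies on chromosome 1. For the germline list camera gave adjusted p = 1.3e-08, or adjusted p = 0.29 with an estimated correlation. Placental genes rose in part. Plac1 was higher (4.29, SE 0.59, adjusted p = 0.00764), as was the pregnancy-specific glycoprotein Psg29 (ratio 29.1, 9.65 to 144), while Tpbpa, a marker of the spongiotrophoblast, was at 358 ± 97.5 against 25.3 ± 29.2 CPM and did not pass (3.85, SE 0.98, adjusted p = 0.216) and Gata3 was at 1.98 (adjusted p = 0.0548). The trophoblast list had 1 of 11 members higher, 3 adjusted over the list alone, and a median of 2.33. For the trophoblast list camera gave adjusted p = 4.8e-05, or adjusted p = 0.46 with an estimated correlation. Pluripotency genes had a median of 0, or 0.38 with bounds, and a mean of −0.02, with 0 of 28 passing over all genes or over the list alone (camera adjusted p = 0.935, direction up). Nanog was at −0.15 (SE 0.51) and Pou5f1 at 0.09 (SE 0.66).

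A few genes of osteoclasts, macrophages, vessels and proliferation were lower in null cultures at day 14. The osteoclast genes Atp6v0d2 (log2 fold change −5.34, SE 0.63, adjusted p = 0.00305) and Ctsk (−4.24, SE 0.66, adjusted p = 0.017) and the macrophage lysozyme Lyz2 (−3.23, SE 0.52, adjusted p = 0.0172) fell, and Csf1r and Cd68 were at −1.5 (adjusted p = 0.0621) and −1.31 (adjusted p = 0.0649). Of 20 blood genes 1 was lower, or 8 lower and 1 higher adjusted over the list alone, with a median of −1.34, or −1.31 with bounds. For the blood list camera gave adjusted p = 0.000575, or adjusted p = 0.57 with an estimated correlation. Among 18 endothelial genes 2 were lower, 3 lower and 2 higher adjusted over the list alone: the sialomucin Emcn, with a ratio of 56.9 (9.79 to 2290), and the angiopoietin receptor Tek (−1.43, SE 0.22, adjusted p = 0.0135), with a list median of −0.55. For the endothelial list camera gave adjusted p = 0.0425, or adjusted p = 0.72 with an estimated correlation. The proliferation marker Mki67 fell by 0.85 (SE 0.15, adjusted p = 0.0229) and topoisomerase Top2a was at −0.8 (SE 0.16, adjusted p = 0.0543). Of 28 cell cycle genes 1 was lower and 0 higher, 11 lower adjusted over the list alone, with a median of −0.5. For the cell cycle list camera gave adjusted p = 1.3e-08, or adjusted p = 0.3 with an estimated correlation. Glycolysis and hypoxia genes had a median of −0.52 with 0 of 22 passing, 7 lower and 1 higher over the list alone. For the glycolysis list camera gave adjusted p = 1.9e-05, or adjusted p = 0.3 with an estimated correlation. Interferon response genes had a median of 1.19 with 0 of 16 passing and 6 higher over the list alone, with Usp18 at 2.58 (adjusted p = 0.116) and Rsad2 at 2.41 (adjusted p = 0.169). For the interferon list camera gave adjusted p = 0.000173, or adjusted p = 0.66 with an estimated correlation. Skeletal muscle genes, with Tnnt3 at −1.75 (adjusted p = 0.0939), had a median of −1.34, or −1.75 with bounds, and 2 lower of 8 over the list alone. For the skeletal muscle list camera gave adjusted p = 0.00273, or adjusted p = 0.29 with an estimated correlation. Parietal endoderm and basement membrane genes, with the laminin Lama1 at 1.39 (adjusted p = 0.0649), had a median of 0.47 and 4 higher of 13 over the list alone. For the parietal endoderm list camera gave adjusted p = 0.00645, or adjusted p = 0.6 with an estimated correlation. Surface ectoderm genes, with the keratin Krt18 at 1.36 (adjusted p = 0.118), had a median of 0.89 and 1 higher of 17 over the list alone. In each of these 3 lists 0 members passed over all genes. For the surface ectoderm list camera gave adjusted p = 0.0223, or adjusted p = 0.75 with an estimated correlation.

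In all, 41 genes were higher and 56 lower at day 14, and 2038 had an unadjusted p under 0.05. Of the 41, 20 lie on chromosomes 1, 6, 8 and 14, whose median lay 0.37 (bootstrap SE 0.014) above that of other autosomes, against 5 of the 56. Without the genes of chromosomes 1, 6, 8, 14 and Y, chosen after seeing the data, 20 were higher and 47 lower. The total of 97 was 50 without either wild type day 8 replicate, 49 and 14 without wild type day 14 replicate 1 and replicate 2, 301 and 297 without null day 8 replicate 1 and replicate 2, and 47 without null day 14 replicate 1. Rybp, Plagl1, Meg3, Ttn, Myh7 and Rnf17 passed without any 1 of the 8 libraries of days 8 and 14. Mki67 (−0.86), Ryr2 (−1.54), Slc8a1 (−1.72), Myom1 (−2.74), Myh6 (−4.68), Tek (−1.42), Lyz2 (−2.84), Ctsk (−2.97), Atp6v0d2 (−4.54), Plac1 (4.47), Pde10a (3.81), Taf7l (4) and Mageb16 (3.97) kept their direction and did not pass without wild type day 14 replicate 2, nor did Emcn, Mael, Syce1, Tdrd1, Tex11 and Psg29. Without wild type day 14 replicate 1 the calls of Mki67 (−0.84), Ryr2 (−1.29), Slc8a1 (−1.37), Myom1 (−2.1), Tek (−1.43), Plac1 (4.15), Pde10a (4.37), Emcn, Psg29, Tdrd1 and Tex11 were lost. Without null day 14 replicate 1 those of Mki67 (−0.78), Ryr2 (−1.65), Slc8a1 (−1.45), Myom1 (−2.36), Tek (−1.2), Ctsk (−3.69), Lyz2 (−2.81), Emcn and Psg29 were lost. Without null day 14 replicate 2 those of Mki67 (−0.93), Ryr2 (−1.21), Slc8a1 (−1.67), Myom1 (−2.55) and Emcn were lost, and without either wild type day 8 replicate those of Mki67 (−0.85), Ryr2 (−1.42), Slc8a1 (−1.56), Myom1 (−2.45), Myh6 (−4.56) and Emcn. Actc1 did not pass without wild type day 8 replicate 1 (−4.77), wild type day 8 replicate 2 (−4.77) or null day 14 replicate 2 (−4.02).

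**Figure D2:**
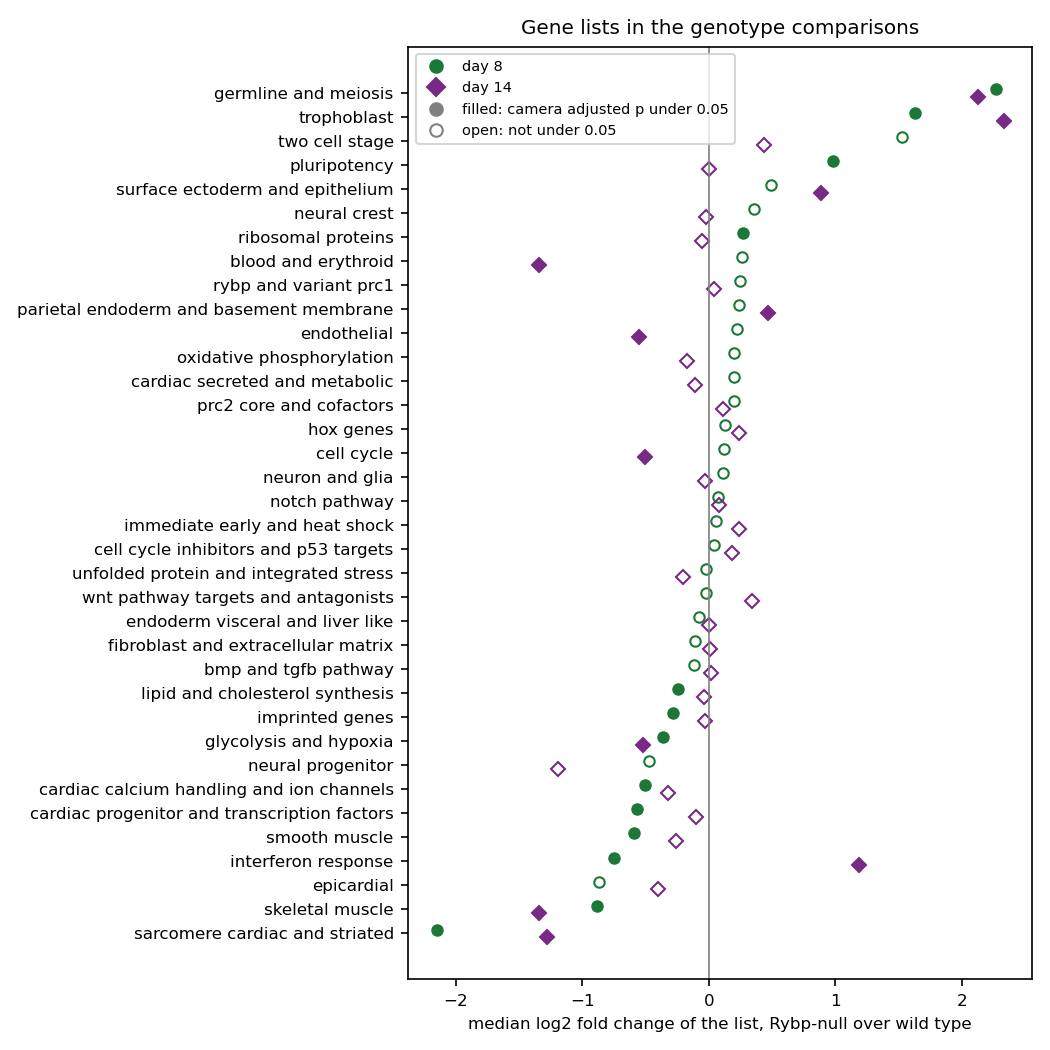
Median log2 fold change of Rybp-null against wild type for 36 gene lists, with green circles for day 8 and purple diamonds for day 14, filled where the camera adjusted p was under 0.05. The sarcomere list lay lowest at day 8 (−2.15), and the germline list was at 2.27 and 2.13.

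Whether the genotype effect differed between days 8 and 14 was asked by the interaction, in which 0 genes passed edgeR's quasi-likelihood test. 962 had an unadjusted p under 0.05, and the DESeq2 Wald test called 6 higher and 2 lower. The smallest adjusted p, 0.0669, belonged to Ttn, whose difference between genotypes was 2.72 log2 units less negative at day 14 (SE 0.35), followed among the named genes by Smyd1 (3.05, SE 0.44, adjusted p = 0.0731). Mki67 had an interaction of −1 (SE 0.21, adjusted p = 0.388), Tnnt2 of 2.32 (SE 0.68, adjusted p = 0.718), Myh6 of 2.64 (SE 1.1, adjusted p = 0.787) and Plagl1 of −0.3 (SE 0.34, adjusted p = 0.964). Without null day 8 replicate 1, null day 8 replicate 2 or null day 14 replicate 1 the interaction gave 2, 1 and 1 higher genes. At list level 8 lists passed camera, 5 upward and 3 downward. The sarcomere list had a median interaction of 1.31 (camera adjusted p = 2.77e-06; adjusted p = 0.29 with an estimated correlation) with 7 of 36 members upward over the list alone and 0 over all genes, and the cell cycle list a median of −0.69 (camera adjusted p = 5.32e-13; adjusted p = 0.29 with an estimated correlation) with 6 of 28 downward over the list alone and 0 over all genes.

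In wild type cells pluripotency genes fell over the first 8 days, and heart and blood genes rose. Tnnt2 rose to 492 ± 39.5 CPM from 0.66 CPM (744-fold, 206 to 6140), Actc1 by at least 376-fold, the embryonic globin Hba-x by at least 650-fold, the adult globin Hba-a1 by at least 188-fold and the platelet and leukocyte protein Plek by at least 318-fold, while Plagl1 rose by a log2 fold change of 7.48 (SE 0.44, adjusted p = 3.29e-07), Myh6 by 4.92 (SE 0.86) and Isl1 31.3-fold (5.44 to 1250). Nanog (−7.54, SE 0.62) and Pou5f1 (−7.13, SE 0.46) fell, and Zfp534, Zfp987, Morc1 and Rpl31-ps13, a pseudogene whose reads may belong to Rpl31, dropped to 0 counts, at least 598-fold, 270-fold, 184-fold and 152-fold lower. Of 28 pluripotency genes 26 fell (median −5.64), with the same count over the list alone. For the pluripotency list camera gave adjusted p = 4.81e-19, or adjusted p = 0.087 with an estimated correlation. Of 20 blood genes 17 rose and 1 fell, with the same counts over the list alone (median 7.36, or 4.98 with bounds). For the blood list camera gave adjusted p = 1.02e-06, or adjusted p = 0.18 with an estimated correlation. Of 36 sarcomere genes 27 rose and 0 fell, 28 over the list alone (median 4.23, or 3.15 with bounds). For the sarcomere list camera gave adjusted p = 6.57e-09, or adjusted p = 0.11 with an estimated correlation. Of 29 cardiac progenitor genes 21 rose, among them Tbx20 (6.2, SE 0.38), and 1 fell, or 22 and 1 over the list alone (median 5.04, or 4.06 with bounds). For the cardiac progenitor list camera gave adjusted p = 1.1e-09, or adjusted p = 0.087 with an estimated correlation. Of 26 germline genes 17 fell, 19 fell and 1 rose over the list alone (median −3.65), with Mael at least 45.5-fold lower. For the germline list camera gave adjusted p = 5.46e-07, or adjusted p = 0.13 with an estimated correlation. In all 3358 genes rose and 3047 fell. With library totals in place of TMM, 3968 rose and 2462 fell. Rybp itself fell by 0.9 (SE 0.32, adjusted p = 0.0413), a call lost without wild type day 8 replicate 1 (−0.82) or replicate 2 (−0.99) and without either wild type day 14 replicate (−0.9).

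In null cells pluripotency genes fell over the same days, and blood and matrix genes and some sarcomere genes rose. Hba-x, Hbb-y and Hba-a1 rose by at least 3000-fold, 558-fold and 449-fold and Postn by at least 4570-fold, and Plagl1 rose by 4.97 (SE 0.42). Nanog (−7, SE 0.59) and Pou5f1 (−5.84) fell, and 26 of 28 pluripotency genes fell, 27 over the list alone (median −5.67). For the pluripotency list camera gave adjusted p = 3.2e-21, or adjusted p = 0.093 with an estimated correlation. Tnnt2 rose by 5.48 (SE 1.02, adjusted p = 0.00393) and Isl1 27.2-fold (4.57 to 1100), whereas Ttn fell by 2.37 (SE 0.29, adjusted p = 5.85e-05), from 132 CPM, and Myh6 by 3.15 (SE 0.95, adjusted p = 0.0292). In wild type cells Ttn, added here after its values were seen, rose by 1.68 (SE 0.3, adjusted p = 0.000949). Of 20 blood genes 14 rose and 2 fell, 15 and 2 over the list alone (median 5.14, or 4.8 with bounds). For the blood list camera gave adjusted p = 7.45e-07, or adjusted p = 0.19 with an estimated correlation. Of 36 fibroblast and matrix genes 30 rose and 1 fell, 30 and 2 over the list alone (median 4.18, or 4.16 with bounds). For the fibroblast list camera gave adjusted p = 2.68e-18, or adjusted p = 0.18 with an estimated correlation. Of 36 sarcomere genes 12 rose and 3 fell, with the same counts over the list alone (median 1.03). For the sarcomere list camera gave adjusted p = 0.0105, or adjusted p = 0.26 with an estimated correlation. Of 29 cardiac progenitor genes 19 rose and 0 fell, 21 over the list alone (median 3.38). For the cardiac progenitor list camera gave adjusted p = 1.63e-09, or adjusted p = 0.081 with an estimated correlation. Of 26 germline genes 22 fell, 23 over the list alone (median −2.83). For the germline list camera gave adjusted p = 4.74e-11, or adjusted p = 0.093 with an estimated correlation. Morc1 and the pseudogenes Rps2-ps13, Rpl30-ps10 and Smt3h2-ps4, whose reads may belong to their parent genes, were at least 98.3-fold, 307-fold, 228-fold and 100-fold lower. In all 3013 genes rose and 2949 fell, and 62.7% of calls were upward with library totals in place of TMM, against 50.5%. That scaling moved the median of all genes from 0.043 to 0.28, and in wild type from 0.125 to 0.334. Of the genes that rose, 2326 were shared with wild type (640 expected of independent lists), and of those that fell 2238 (568 expected). The Myh6 call was lost without either wild type day 8 replicate (−3.15), null day 8 replicate 1 (−2.62) or null day 8 replicate 2 (−3.84).

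From day 8 to day 14 embryonic globins fell and part of the matrix genes rose in both genotypes. In wild type cultures the retinal dehydrogenase Aldh1a1 rose 349-fold (96.1 to 2880) and C1qa, Clec12a and Mgst1 by at least 41.4-fold, 39.2-fold and 76.3-fold. Of 36 fibroblast and matrix genes 13 rose and 2 fell in wild type and 17 rose and 2 fell in null cultures, or 21 and 2 and 22 and 2 over the list alone. The medians were 0.98 (camera adjusted p = 3.61e-07, or adjusted p = 0.53 with an estimated correlation) and 1.27 (camera adjusted p = 3.66e-09, or adjusted p = 0.46 with an estimated correlation). In wild type cultures Hbb-y, Hbb-bh0, Hbb-bh1 and the red cell anion exchanger Slc4a1 were 516-fold (142 to 4260), 260-fold (46.2 to 10300), 144-fold (49 to 702) and 109-fold (36.9 to 531) lower. Ttn (−1.77, SE 0.24), Smyd1 (−2.2) and Isl1 (−3.35, adjusted p = 0.0183) fell, while Tnnt2 was at −0.72 (adjusted p = 0.519) and Plagl1 at 0.85 (adjusted p = 0.0707). In null cultures the placental genes Tpbpa (8.77, SE 1.44, adjusted p = 0.0332), Tpbpb (at least 47.7-fold) and Prl2b1 (at least 61.4-fold) and the interferon-induced Ifit1 (at least 36.1-fold) rose, and Hbb-bh1 (at least 363-fold), Hbb-bh0 (at least 189-fold), Hba-x (−10.38) and Hbb-y (−8.92) fell. Isl1 was 34.9-fold lower (5.87 to 1420), Ttn rose by 0.96 (SE 0.26, adjusted p = 0.0442), and Tnnt2 was at 1.6 (adjusted p = 0.102). Of 28 cell cycle genes 20 fell in null cultures, with Mki67 at −1.51 (adjusted p = 0.000154), or 25 over the list alone (median −1.09; camera adjusted p = 1.84e-18; adjusted p = 0.37 with an estimated correlation), against 1 in wild type, also 1 over the list alone (median −0.45; camera adjusted p = 6.68e-07; adjusted p = 0.46 with an estimated correlation). Of 16 interferon response genes 10 rose in null cultures, 15 over the list alone (median 2.49, or 2.43 with bounds; camera adjusted p = 4.77e-10; adjusted p = 0.46 with an estimated correlation), against 3 in wild type, also 3 over the list alone (median 0.91; camera adjusted p = 0.0165; adjusted p = 0.81 with an estimated correlation). In wild type 390 genes rose and 249 fell, and in null cultures 678 and 539, with 269 (16.7 expected) and 136 (8.48 expected) shared. The wild type total of 639 was 177 and 108 without its day 8 replicates 1 and 2, and 309 and 131 without its day 14 replicates 1 and 2. The null total of 1217 was 613 without null day 14 replicate 2. The null Ttn call was lost without any 1 wild type library (0.95 to 0.96), null day 8 replicate 1 (0.66) or null day 14 replicate 2 (0.68). The Tpbpa call was lost without any 1 of the 4 null libraries (8.17 to 10.12), that of Hba-x without null day 14 replicate 2 (−9.31), that of Prl2b1 without null day 8 replicate 1, that of null Isl1 without null day 14 replicate 2, that of wild type Isl1 without any 1 of its 4 libraries (−4.26 to −2.74), that of Clec12a without wild type day 8 replicate 1 or 2 or day 14 replicate 2 and that of Mgst1 without either wild type day 8 replicate.

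The calls of the 2 genotype comparisons overlapped. These share no library, but the same fit gave each gene's spread for all comparisons, so their calls are not fully independent. 15 genes were higher at both days (0.207 expected of independent lists, one-sided Fisher's exact test p = 5.16e-25) and 30 were lower at both days (0.425 expected, p = 2.82e-50), and all 45 genes called at both days went in the same direction. Genes that rose by day 8 in wild type cells were over-represented among those lower in null cultures at day 14, with 36 of 56 (11.9 expected, two-sided Fisher's exact test p = 4.09e-12), and genes that fell by day 8 were over-represented among those higher, with 16 of 41 (7.9 expected, p = 0.00427). By the same two-sided exact test, the other pairings gave 14 risen genes among the higher (8.7 expected, p = 0.0542) and 9 fallen genes among the lower (10.8 expected, p = 0.615). Genes are not independent of each other, so these p-values describe the lists only. The expected numbers were also not matched on the level in wild type cultures. A gene called lower must be well expressed in wild type at day 14, which favours genes that had risen. The reverse holds for genes called higher. Part of the over-representation of risen and fallen genes may therefore be built in, and these tests cannot tell how much.

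The shift of chromosomes 1, 6, 8 and 14 was present at each day, with a median log2 ratio of null to wild type above that of other autosomes by 0.4 at day 0, 0.35 at day 8 and 0.37 at day 14 (bootstrap SE 0.014, 0.011 and 0.014). Chromosome 1 stood highest, with medians of 0.55, 0.43 and 0.44 at the 3 days, followed by chromosome 14 with 0.41, 0.39 and 0.37, chromosome 6 with 0.29, 0.23 and 0.2 and chromosome 8 with 0.27, 0.14 and 0.1. The medians of the other autosomes lay between −0.11 and −0.01 at day 8. Each null library showed the shift on its own, from 0.31 to 0.4, and each wild type library of days 8 and 14, set against its replicate, lay between −0.01 and 0.01. These chromosomes were singled out after their values were seen.

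**Figure D3:**
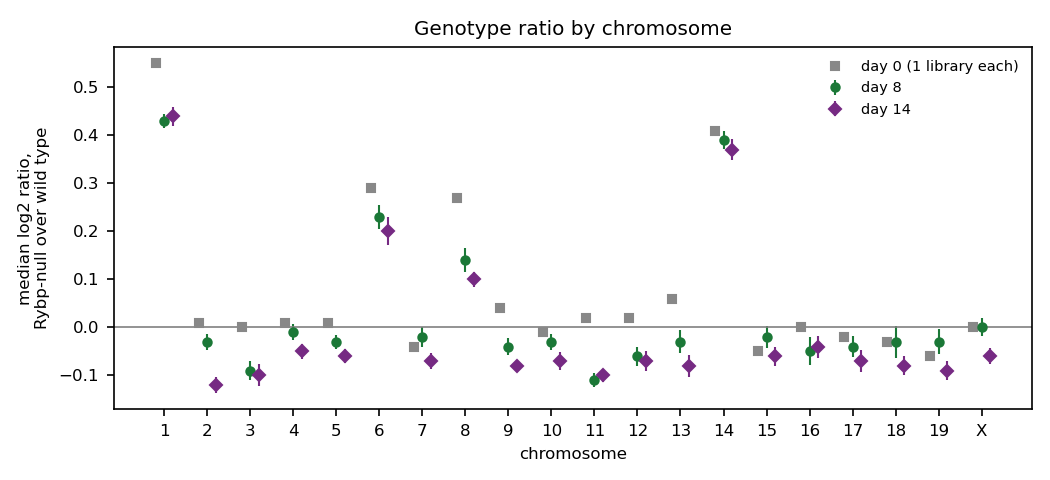
Median log2 ratio of Rybp-null to wild type for the genes of each chromosome, with grey squares for day 0, circles for day 8 and diamonds for day 14; error bars are bootstrap SEs at days 8 and 14. Chromosome 1 stood at 0.55, 0.43 and 0.44 at the 3 days.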

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

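All 8 results here come from a test of the difference itself, planned before the data were examined: the change of the genotype effect from day 8 to day 14 over each gene list, tested with camera. In each of them 0 members passed edgeR's quasi-likelihood test over all genes (962 genes had an unadjusted p under 0.05), and none passed with a correlation estimated from the data, so each rests on the preset correlation of 0.01.

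The cell cycle list moved down, with a median interaction of −0.69 (camera adjusted p = 5.32e-13; adjusted p = 0.29 with an estimated correlation): Mki67 was at −1 (SE 0.21) and Top2a at −0.78 (SE 0.23). Interferon response genes moved up, with a median of 2.2 (camera adjusted p = 3.81e-09; adjusted p = 0.58 with an estimated correlation). Sarcomere genes moved up by a median of 1.31 (camera adjusted p = 2.77e-06, or adjusted p = 0.29 with an estimated correlation), with Ttn at 2.72 (SE 0.35). The gap to wild type was narrower at day 14, which does not by itself mean a rise in null cultures. From day 8 to day 14 mean Ttn went from 1090 to 320 CPM in wild type and from 25.6 to 49.3 CPM in null cultures. Mean Tnnt2 went from 492 to 299 CPM in wild type and from 46.2 to 142 CPM in null cultures. Cardiac progenitor genes, with Smyd1 at 3.05 (SE 0.44), had a median of 0.52 (camera adjusted p = 0.000132; adjusted p = 0.29 with an estimated correlation) and genes of calcium handling, with Slc8a1 at 1.53 (SE 0.42), a median of 0.48 (camera adjusted p = 0.0444; adjusted p = 0.5 with an estimated correlation). Ribosomal protein genes had a median of −0.27 (camera adjusted p = 0.000503, or adjusted p = 0.63 with an estimated correlation). Pseudogenes may share reads with them, so this value is uncertain. Oxidative phosphorylation genes had a median of −0.27 (camera adjusted p = 0.00654, or adjusted p = 0.35 with an estimated correlation). Parietal endoderm and basement membrane genes had a median of 0.36 (camera adjusted p = 0.0194, or adjusted p = 0.74 with an estimated correlation).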

How the results depend on the processing

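Without a filter on low counts the calls were 376 higher and 332 lower at day 8, 344 and 293 at day 14, 39 and 26 for the interaction, 770 and 474 for wild type day 14 against day 8 and 1037 and 855 for the null cells. The DESeq2 Wald test gave 126 higher at day 8, 100 higher and 100 lower at day 14 and 6 and 2 for the interaction. At day 8, 41 genes were higher with the replicate number as a block and 40 with the 4 libraries of that day only. Without genes of chromosomes 1, 6, 8, 14 and Y, chosen after seeing the data, 24 were higher and 76 lower at day 8 and 20 higher at day 14. Leaving out single libraries gave 5 to 188 higher and 23 to 147 lower at day 8, 3 to 138 and 11 to 163 at day 14, 0 to 2 higher for the interaction, 62 to 555 and 35 to 384 for wild type day 14 against day 8, and 383 to 623 and 230 to 620 for the null cells. With an estimated correlation 0, 0 and 0 lists passed at day 8, at day 14 and for the interaction, and with fry 7, 3 and 0. At day 0 a minimum of 1 CPM gave 350 genes at least 4-fold higher and 132 lower. Of the alternatives run for the named genes, 2581 left a call as it was, 180 lost it, 102 gained it and 19 turned a direction, all 19 for genes that had not passed; for lists passing at days 8 and 14 and in the interaction, 99 kept the call, 61 lost it and 0 turned. Over the fits without a single library the direction turned at day 14 for Nanog (−0.84 to 0.33) and Pou5f1 (−0.72 to 0.65), in the interaction for Myh6 (−0.09 to 3.59), Plagl1 (−0.85 to 0.1) and Yaf2 (−0.32 to 0.22), in wild type day 14 against day 8 for Nanog (−0.03 to 0.82), Pou5f1 (−0.38 to 0.37) and Yaf2 (−0.22 to 0.32), and in null day 14 against day 8 for Myh6 (−0.65 to 3.02) and Yaf2 (−0.18 to 0.2). Yaf2 also turned in the interaction with library totals (0.01), and in null day 14 against day 8 with the 8 libraries of days 8 and 14 (0). The cause was not tested.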

Other observations

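Of the tests in this part, those of depth at day 0, of a few strongly changed genes, of leftover ES cells, of a delay, of the whole of chromosome 6 and both tests of a lower share of cardiomyocytes alone were chosen after the result was seen, as were the genes and chromosomes singled out here. Transcripts of the Y chromosome differed in part. Ddx3y, a helicase, was lower in null cultures at day 8 (log2 fold change −3.26, SE 0.32, adjusted p = 0.000496) and day 14 (−4.23, SE 0.35, adjusted p = 0.00015), and Uty, a demethylase paralog, at −2.92 (SE 0.39, adjusted p = 0.00381) and −2.54 (SE 0.37, adjusted p = 0.0127), with day 0 ratios of −2.54 and −2.68; Eif2s3y, on the same chromosome, was at 0.07, −0.21 and −0.24. In the Meg3 region of chromosome 12, Rtl1 was lower with Meg3, at −1.78 (SE 0.38, adjusted p = 0.0455) and −2.62 (SE 0.41, adjusted p = 0.0136), while Dlk1 was at 0.77 (SE 0.68) and 0.48 (SE 0.67) and did not pass. Since the strand setting is not given, antisense reads cannot be told apart from those of Rtl1, and its change is uncertain. Among other imprinted genes H19 (1.19, SE 0.15, adjusted p = 0.00502) and Grb10 (1.12, SE 0.17, adjusted p = 0.0135) were higher at day 14. Plagl1 and Meg3 were already lower in the null ES cells, at 4.91 against 66.3 CPM and 24.5 against 347 CPM in 1 library each.

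Genes of chromosomes 1, 6, 8 and 14 were on the whole higher in null libraries at each day. After correction for GC content and gene length the shift was 0.36 at day 8 (bootstrap SE 0.011) and 0.37 at day 14, which argues against these as its cause; it was 0.35 and 0.37 without correction at days whose libraries are of similar depth, for the same 4 chromosomes that rank highest by day 0 alone, which argues against the deeper day 0 null library as the whole cause. A few strongly changed genes are argued against by the lower quartile of these chromosomes, which stood 0.3 (bootstrap SE 0.013) above that of other autosomes at day 8 and 0.31 at day 14; a share of genes above the median, looked at first, was fixed by the choice of chromosomes and is not used. Extra copies of these chromosomes in the null cell line stay open. At days 8 and 14, 38 and 37 of 40 windows of consecutive genes lay above the median of other autosomes, against 72 and 71 of 150 on other autosomes. That met the count predicted before the result, and all 10 windows of chromosome 1 and all 10 of chromosome 14 lay above it at both days. However, 2 adjacent windows of chromosome 6 did not. Choosing chromosomes by their medians also favours a high count, a reason given after it was seen, although the same 4 rank highest by day 0 alone. A copy of the whole of chromosome 6 is argued against by 2 of its 10 windows, adjacent to each other, which at day 8 lay below the rest of the chromosome by −0.37 (SE 0.063) and −0.35 (SE 0.071). Since each genotype is a single cell line, effects of Rybp and other differences between the lines stay open for every result.

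In null cultures 7 of 26 germline genes were higher at day 8 and 8 at day 14, with 0 lower at either day. The list passed camera at both days but not with an estimated correlation. The shift of chromosomes 1, 6, 8 and 14 is argued against by the 19 members on other chromosomes, whose median at day 8 was 2.65 (bootstrap SE 1.1). Leftover ES cells would hold germline and pluripotency transcripts in the proportions of day 0, yet from day 0 germline genes fell less than pluripotency genes, by 3.13 log2 units (SE 0.77) to day 8 and by 3.33 (SE 1.1) to day 14, among genes of at least 50 CPM at day 0. A minimum of 5 CPM had been set first and gave 2.19 (SE 0.61) and 1.84 (SE 0.55); it was raised after these values were seen, because genes near 0 counts cannot fall further. The smaller fall of germline genes speaks against leftover ES cells only as the sole source of these transcripts. In wild type cells, too, the germline list fell less than the pluripotency list by day 8. The gap therefore does not decide whether leftover ES cells added to the germline excess of null cultures. Such an addition, an effect of Rybp and a difference between the cell lines stay open.

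In null cultures at day 8, 14 of 36 sarcomere genes were lower and 0 higher. The list passed camera but not with an estimated correlation. Scaling is argued against by a list median of −2.18 (bootstrap SE 0.86) with library totals and −2.17 with DESeq2 size factors, and a delay made up by day 14 by null cultures of day 14 standing at −1.57 (SE 0.53) against wild type day 8, although a rise and fall between the sampled days was not measured. Fewer cardiomyocytes with the same transcripts in each would lower all members alike; the SD over 25 members was 2.68 against a median SE of 0.54, but the test also asked, before the result, that no member be made by other cells, and 5 of the 25 stood at 5 CPM or more in both ES cell libraries, with Tpm1 at 264 CPM in null and 821 CPM in wild type cells. These 5 do not account for the spread, as the SD over the other 20 was 2.48 against a median SE of 0.62; what other cells of day 8 cultures add to those 20 was not measured. A lower share of cardiomyocytes alone would raise all other cell types alike. The medians of 11 lists of other cell types spanned 2.5 (SE 1.5), which left it open. A test of the spread of all 11, added later, gave chi-square p = 0.00372, with endothelial genes at 0.22 (SE 0.12) and smooth muscle genes at −0.59 (SE 0.2). It does not decide the question, because its SEs are over genes and leave out the spread between libraries. The smooth muscle list also shares Des and Myocd with the heart lists, so fewer cardiomyocytes could lower it too. Without the smooth muscle and epicardial lists p was 0.15, but these were known to be the 2 lowest when they were left out, and that value is not used. Fewer cardiomyocytes, alone or together with changes in other cell types, and lower expression within cardiomyocytes stay open.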
